A study of Auricularia auricula-judae with 2 samples.

How the data were processed

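Total RNA from fruit bodies of Auricularia auricula-judae was sequenced by the authors as 2 libraries, 1 from fruit bodies of unirradiated mycelium and 1 from fruit bodies of mycelium that had received 200 Gy of gamma radiation. Per the labels, both groups grew for 14 days at 25 °C on agar, then for 30 days at 25 °C on sawdust and rice bran, and fruited at 18 °C and 90% humidity, and 1000 ng of RNA went into each library. The libraries were assigned to the groups by the sample descriptions that the column headers repeat.

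The deposited table holds 1 line per assembled transcript, with 2 columns of FPKM made by the authors (fragments per kilobase of transcript, scaled to the size of the library), given to 2 decimals. The assembler, aligner and quantification tool are not given in the sources used here. The authors also deposited a log2 fold change, which equals the log2 ratio of 2 further values in the table where both are above 0. Those 2 values, of another unit that the authors' headers do not name, behave as estimated read counts divided by a factor per library, and carry no sample name. They were used only as the authors' own comparison and as a measure of depth, and their sum is called scaled reads. The p-value and q-value columns are the authors' own, per the file headers, and the test behind them is not given in the sources used here. Descriptions and symbols come from the Swiss-Prot matches in the deposited table, which 21855 of 57717 transcripts have, so a symbol names the closest match, often from a distant organism, and not a curated gene of this fungus. No genome coordinates were used here.

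The log2 ratio of irradiated over control was computed from FPKM + 1, among transcripts with a mean of 1 FPKM or more over both libraries, and a transcript was counted as higher or lower from a 2-fold ratio. With 1 library per group there is no replicate spread, so no p-value was computed. Ratios of scaled read counts and scaling by the library total alone had been planned and were not applied, since the table holds no read counts. A gene listed at 0 in 1 library is named as such, without a fold. The ratio of the authors' scaled values got an exact Clopper-Pearson 95% interval on rounded values. It covers counting error only, and leaves out differences between fruit bodies, harvests and library preparations. It belongs to the scaled values, so an FPKM ratio can lie outside it. Over transcripts, the FPKM log2 ratios differ from those of the scaled values by a median of 0.07. Where isoforms are summed, as described below, the gap can be larger and the signs can differ. For example, cel2 (TBIU025580) had an FPKM log2 ratio of 0.77 and an interval of -0.54 to -0.08.

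The 22 gene lists were fixed before the data were examined as text patterns matched to descriptions, with no correction for wrong matches. Each list's median log2 ratio got its percentile among 10000 random lists of the same size matched on deciles of the mean log value, as a description of these 2 libraries. Lists with fewer than 5 members would get values only. Bars around list medians are 95% order-statistic intervals. The rule for named transcripts, also fixed beforehand, took the 12 highest and 12 lowest log2 ratios among described transcripts above the median level, the 2 highest and 2 lowest of each list, and the 5 most abundant of each library. It picked mainly transcripts with few reads: of the 84 picked from lists, 66 had under 20 scaled reads and 74 were listed at 0 in 1 library.

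After the values had been seen, a second set of results was therefore added. FPKM and scaled values were summed over the isoforms of each assembled gene, and genes with 100 or more scaled reads were kept. Genes of 1 assembly cluster, by the first part of their assembly names, were kept apart. Some genes named or counted here, among them MEP, coq2, hsp16 and HHT2 genes, share a cluster and may not be independent. The 12 genes in each direction with the interval bound furthest from 0 were named. The 3 highest and 3 lowest of each list were picked, and the text gives some of them. Members at least 2-fold apart in the DNA repair, antioxidant, chaperone, pigment and cell cycle lists were added, genes down to rank 40 were looked at for further observations, hspA and SC3 were named as members that text patterns had missed, and RPL10 as a second abundant ribosomal protein gene. Minimums of 20 and 100 scaled reads, isoform summing, removal of a running median over 20 bins of estimated transcript length, the isoform with the most reads alone, and the small heat shock set were also added then. The alternatives planned beforehand were median-centred ratios, no filter, a mean of 10 FPKM or more, pseudocounts of 0.1 and 5, the authors' scaled values, and lists without members shared between lists.

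The counting of 2-fold genes was tested on simulated data with counting error only, over 8249 genes. All 50 genes at each of the log2 shifts of -3, -1.5, 1.5 and 3 were counted as 2-fold apart, as was 1 of 8049 genes with no shift. The list step was tested on ratios drawn independently per gene from a normal distribution. Of 40 unshifted lists of 45 genes picked at random, 2 lay outside the central 95% of random lists. Independent genes give about that rate by construction, so the check does not cover lists whose members vary together. Depth per transcript was low: the median transcript past the filter had 10.3 scaled reads, 57.4% had under 20 and 24.0% had 100 or more. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.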

Results

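Fruit bodies of the wood-ear mushroom Auricularia auricula-judae were profiled by RNA-seq in 2 groups. In 1 group the mycelium had received 200 Gy of gamma radiation on agar plates before it was moved to sawdust and fruited, and in the other it had not. RNA came from the fruit bodies, so the values describe tissue grown after the exposure and not the mycelium at the time of it. Each group had 1 library, so no difference given here has a replicate check, and no test was run between the libraries. The deposited values cover 57717 assembled transcripts of 43428 assembled genes, of which 42825 transcripts were above 0 FPKM in the control library and 44921 in the irradiated library. The FPKM values summed to 970111 in the control library and 983895 in the irradiated library, and the 10 most abundant transcripts held 7.0% and 7.18% of these sums. Raw read totals are not in the deposited values. The authors' pair of scaled values per transcript summed to about 8872430 and 8404060, and their sum per gene is called scaled reads here.

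The comparison addressed how fruit bodies differ after gamma irradiation of the mycelium they grew from. Among assembled genes with 100 or more scaled reads, those furthest above the control included oxidases and transporters. A gene described as bilirubin oxidase (BLRO_MYRVE, TBIU011885), a multicopper oxidase, had 4.12 FPKM in the control library and 113 FPKM in the irradiated library, a log2 ratio of 4.48 with a 95% counting interval of 4.30 to 5.04. Laccase-2 (lcc2, TBIU046262), a multicopper oxidase that oxidises phenols, had 71.98 FPKM in the control and 406 FPKM in the irradiated library (log2 ratio 2.48). A gene described as glutathione transporter 1 (pgt1, TBIU012296), which carries the thiol peptide glutathione across membranes, had 35.3 FPKM in the control and 426 FPKM in the irradiated library (log2 ratio 3.56). A more abundant pgt1 gene (TBIU066844) had 2039 FPKM in the control and 1808 FPKM in the irradiated library (log2 ratio -0.17). Further pgt1 genes (TBIU022496 and TBIU021005) had log2 ratios of 0.83 and 0.37. An E3 ubiquitin ligase described as HERC2 (TBIU007720) was listed at 0 in the control library and at 15.6 FPKM in the irradiated library.

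The next genes of the 12 above the control included several enzymes. Maleylacetoacetate isomerase (mai, TBIU011357), an enzyme of tyrosine breakdown, had 1.05 and 21.2 FPKM in the control and irradiated libraries. Quercetin 2,3-dioxygenase (yhhW, TBIU010411) had 51.6 and 325 FPKM, a log2 ratio of 2.63. The 4-hydroxybenzoate polyprenyltransferase of ubiquinone synthesis (coq2, TBIU057900) had 24.9 and 151.6 FPKM, a log2 ratio of 2.56. Kynurenine aminotransferase (AADAT, TBIU014365) had 11.0 and 65.0 FPKM. The remaining genes of this group were the transporter AQR1 (TBIU006742, log2 ratio 3.09), the allergen homolog ALTA7 (TBIU012846, 2.81), sphingomyelin phosphodiesterase (Smpd1, TBIU020823, 2.64) and cellobionic acid phosphorylase (XCC4077, TBIU008171, 2.37).

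The genes furthest below the control included small heat shock proteins and a secreted protease. A gene described as heat shock protein 16 (hsp16, TBIU009017), a small chaperone that binds unfolded proteins, had 553 FPKM in the control and 30.1 FPKM in the irradiated library, a log2 ratio of -4.16 with a 95% counting interval of -4.49 to -4.07. A second hsp16 gene (TBIU022657) had 1512 and 121 FPKM (log2 ratio -3.63), and the class I small heat shock gene HSP17.9A (TBIU000140) had 557 and 59.5 FPKM (log2 ratio -3.20). Peptidyl-Lys metalloendopeptidase (MEP, TBIU018746), which cuts proteins before lysine, was among the most abundant transcripts of the control library at 5249 FPKM and had 742 FPKM in the irradiated library (log2 ratio -2.82). A second MEP gene (TBIU058247), of the same assembly cluster, had 1069 and 175 FPKM (log2 ratio -2.60).

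Ferric reductase component FRE3 (TBIU051249), which reduces iron before its uptake, had 38.8 and 2.35 FPKM in the control and irradiated libraries. The mitochondrial succinate/fumarate transporter SFC1 (TBIU014877) had 44.0 and 2.68 FPKM, a log2 ratio of -3.61. A zinc-type alcohol dehydrogenase-like gene (SPAPB24D3.08c, TBIU013480) had 182 and 24.0 FPKM. The others were HSP12 (TBIU007084, log2 ratio -3.22), 1 copy of the ribosomal protein gene RPL24 (TBIU029506, -3.98), a histone methyltransferase homolog (Prdm9, TBIU011015, -2.70) and the kinase homolog Cdkl4 (TBIU024825, -2.68). These 12 genes above and 12 below were picked by a rule set after the values had been seen, and their counting intervals leave out any difference between fruit bodies.

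**Figure D1:**
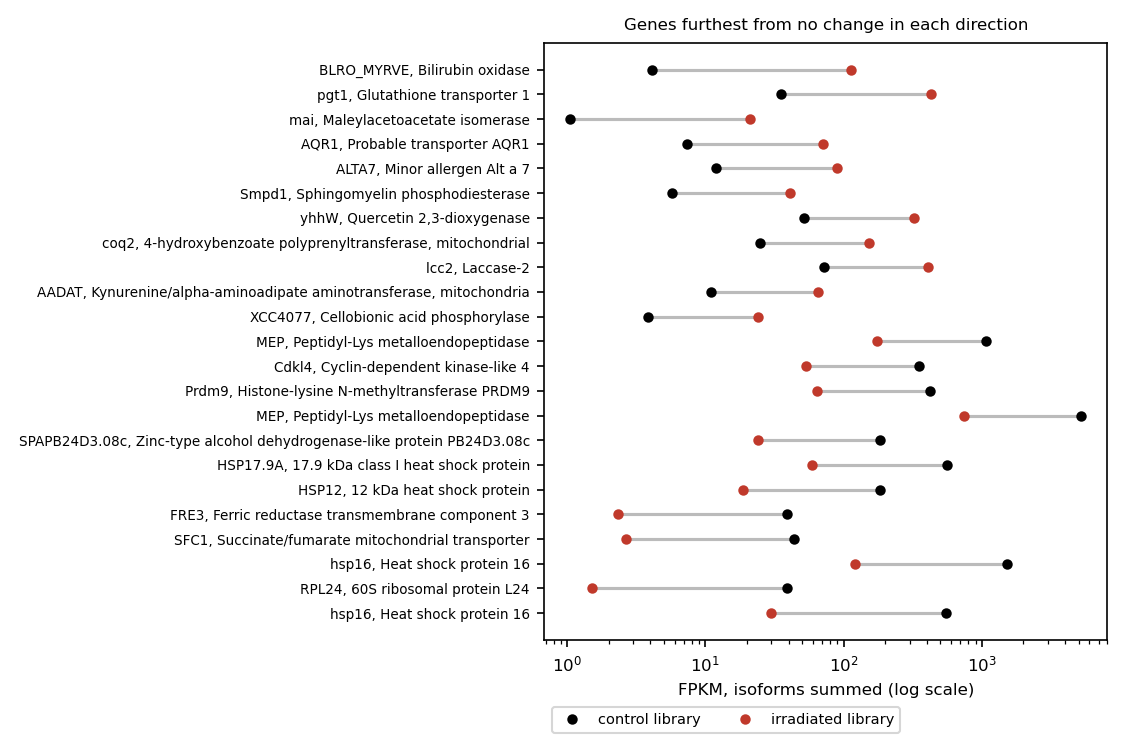
FPKM in the control library (black) and the irradiated library (red) of the genes furthest above and below the control, with isoforms summed, on a log scale; HERC2, listed at 0 in the control, is left out. The genes lower in the irradiated library include 2 hsp16 genes at 553 and 1512 FPKM in the control, and those higher include laccase-2 at 406 FPKM in the irradiated library.

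Of 47128 transcripts with a mean of 1 FPKM or more, 14893 (31.6%) were at least 2-fold higher and 12289 (26.1%) at least 2-fold lower in the irradiated library. Most of these had few reads: 77.8% had under 20 scaled reads, and 19594 were listed at 0 in 1 library. With isoforms summed and 100 or more scaled reads, 8249 assembled genes remained measured, of which 769 (9.32%) were at least 2-fold higher and 716 (8.68%) at least 2-fold lower. Of these, 365 higher and 231 lower genes had an informative description. The median log2 ratio of the 8249 genes was 0.10, and with this shift removed 598 genes were higher and 853 lower, so which direction held more genes depended on the scaling. The genes with 100 or more scaled reads held 98.0% of all scaled reads, and the median half-width of their 95% counting intervals was 0.24 on the log2 scale. Of those at least 2-fold apart in FPKM, 5 had a counting interval that covered 0.

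The rule fixed before the data were examined took the transcripts with the most extreme FPKM ratios. Its 12 transcripts furthest above the control were all listed at 0 in the control library, and 10 of them had under 20 scaled reads. Of its 12 furthest below, 10 were listed at 0 in the irradiated library and 9 had under 20 scaled reads. One of these, an isoform of the ubiquitin ligase gene Ccnb1ip1 (TBIU015469), had a log2 ratio of -5.56, which became 0.21 once the isoforms of its gene were summed. The described transcript with the highest FPKM in the control library was allantoicase (SPAC1F7.09c), an enzyme of purine breakdown, at 9585 FPKM in the control and 6662 FPKM in the irradiated library. In the irradiated library it was the ribosomal protein gene RPS25A (TBIU002740), at 5912 FPKM in the control and 11418 FPKM in the irradiated library.

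**Figure D2:**
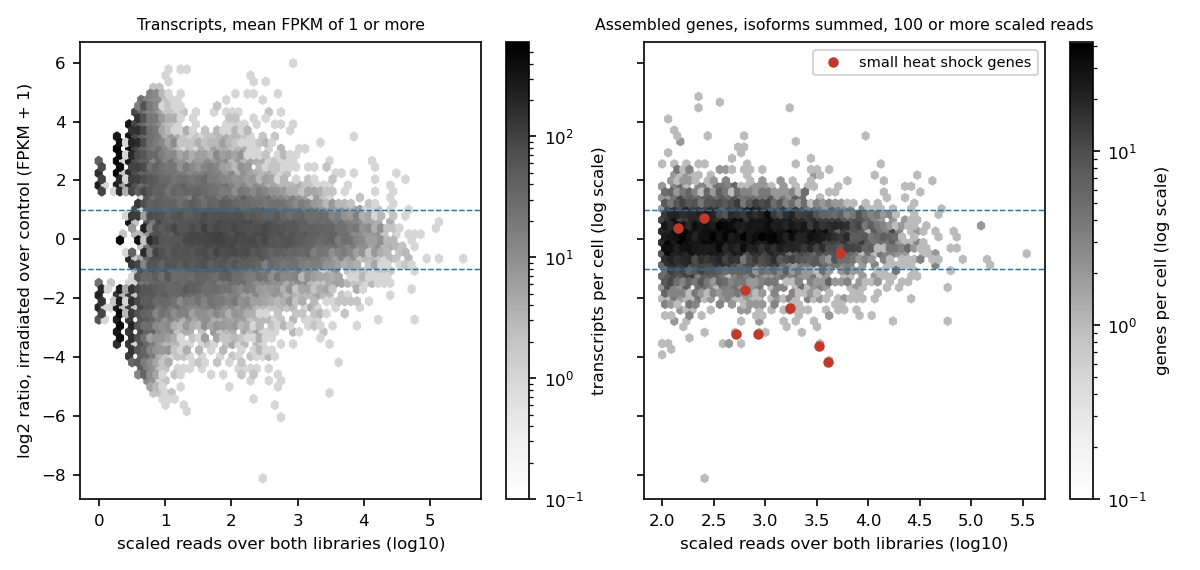
Log2 ratio of irradiated over control (FPKM + 1) against scaled reads over both libraries (log10), for transcripts with a mean of 1 FPKM or more (left, values under 1 read drawn at 1) and for assembled genes with isoforms summed and 100 or more scaled reads (right); shading counts items on a log scale and dashed lines mark 2-fold. The spread is widest at few reads, and of the 9 genes taken as small heat shock genes (red) 6 lie at least 2-fold below the control.

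DNA repair and damage response genes were higher as a group in the irradiated library. Of 46 such genes with 100 or more scaled reads, 7 were at least 2-fold higher and 1 was at least 2-fold lower, and the list's median log2 ratio of 0.57 lay at percentile 99.99 of random lists matched on expression. Flap endonuclease 1-A (FEN11, TBIU023028), which trims DNA flaps in replication and base excision repair, had 18.4 FPKM in the control and 71.8 FPKM in the irradiated library (log2 ratio 1.91). MRE11 (TBIU017545) and Rad50 (TBIU025662), partners in a complex that binds broken DNA ends, had log2 ratios of 1.43 and 1.05, with MRE11 at 2.96 FPKM in the control and 9.7 FPKM in the irradiated library. The others at least 2-fold higher included rad8 (TBIU023249, log2 ratio 1.39) and 1 gene of the damage checkpoint protein hus1 (TBIU003273, 1.20). They also included the excision repair nuclease rad13 (TBIU025820, 1.10, and 0.73 for its isoform with the most reads alone) and the DNA ligase adl1 (TBIU021362, 1.0). The counting intervals of Rad50, this hus1 gene, rad13 and adl1 reached below 2-fold. A second hus1 gene (TBIU003272) had 14.3 and 13.3 FPKM (log2 ratio -0.09). The most abundant genes of the list were lower. The postreplication repair ligase RAD18 (TBIU016514) had 375 FPKM in the control and 138 FPKM in the irradiated library (log2 ratio -1.43). An MLH3 gene (TBIU015139) had 399 and 332 FPKM (log2 ratio -0.26), and the helicase ercc3 (TBIU019654) had 205 and 134 FPKM (log2 ratio -0.61). A second MLH3 gene (TBIU021737) had a log2 ratio of -0.37. At the level of transcripts the list held 140 members with a median of 0.45, at percentile 99.6. Its text pattern also matched the mitotic checkpoint genes mad1 (TBIU023002, log2 ratio 0.36) and Bub3 (TBIU005297, 0.56), and Nbr1 (TBIU021953, -0.27) by its name alone. With the overall shift of 0.10 removed, 4 of the 46 genes were at least 2-fold higher and the list median was 0.47.

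Antioxidant enzymes went both ways. Of 42 genes, 8 were at least 2-fold higher and 2 at least 2-fold lower in the irradiated library. Besides the pgt1 gene TBIU012296, a glutaredoxin-like gene (YD286_MOUSE, TBIU047312) had a log2 ratio of 1.79. Peroxiredoxin 1 (Jafrac1, TBIU011458), which reduces peroxides, had 34.8 and 98.6 FPKM in the control and irradiated libraries. Cytochrome c peroxidase (CCP1, TBIU013759), which removes hydrogen peroxide in mitochondria, had 365 FPKM in the control and 849 FPKM in the irradiated library (log2 ratio 1.21), and glutathione reductase (gtr-1, TBIU008583) had 71.9 and 168 FPKM. A catalase gene (cta1, TBIU020200), whose product breaks down hydrogen peroxide, had 65.4 FPKM in the control and 19.7 FPKM in the irradiated library (log2 ratio -1.69). The other lower gene was a peroxiredoxin Q (PRXQ, TBIU023075, log2 ratio -1.05), whose isoform with the most reads had a log2 ratio of 0.42 on its own. The list median was 0.42 over 200 transcripts, at percentile 98.5, and 0.18 over the 42 genes, at percentile 73.5, so the list stood apart from random lists only at the level of transcripts.

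Of 9 genes taken here as small heat shock genes, by descriptions naming heat shock protein 16, a small heat shock protein or a heat shock protein of 12 to 17.9 kDa, 6 were at least 2-fold lower in the irradiated library, with a median of 431 FPKM in the control and 51.0 FPKM in the irradiated library. Their log2 ratios ranged from -4.16 to 0.73 over the 9 genes, with a median of -2.32. Small heat shock protein C4 (hspc4-1, TBIU015441) had 216 and 42.4 FPKM, and a second HSP12 gene (TBIU038110) had 309 and 93.2 FPKM. The set went by description and size and not by protein family. Its HSP12 genes (TBIU007084, TBIU038110 and TBIU005521, log2 ratios -3.22, -1.72 and 0.40) are described only as 12 kDa heat shock proteins. Whether these belong to the small heat shock family was not checked. A further hsp16 gene (TBIU022656), the most abundant of the set, had 2517 FPKM in the control and 1818 FPKM in the irradiated library (log2 ratio -0.47). The spore protein gene hspA (TBIU022655), which belongs to the small heat shock family but was not in the set, had 424 and 449 FPKM (log2 ratio 0.08). This gene and the hsp16 genes TBIU022656 and TBIU022657 share an assembly cluster, and reads shared between them were not tested. The 51 other chaperone genes had a median log2 ratio of 0.21, with 4 at least 2-fold higher and 2 at least 2-fold lower. The lower genes were SSB1 (TBIU035749, log2 ratio -1.28) and the heat shock gene DDB_G0280215 (TBIU008361, -2.37), whose description gives no size. Those higher included 2 genes of the chaperone HSP90 (TBIU002339 and TBIU008095), with log2 ratios of 1.05 and 1.19. Heat shock protein 104 (hsp104, TBIU028326), also outside the small heat shock set, had 752 and 381 FPKM. Its log2 ratio of -0.98 was just within 2-fold, and its counting interval of -1.41 to -1.32 lay beyond 2-fold. With the overall shift removed, 2 genes of the chaperone list were at least 2-fold higher and 9 at least 2-fold lower, and the first of these HSP90 genes was within 2-fold. The whole chaperone list of 60 genes had a median of 0.16, at percentile 72.2. The small heat shock set was picked from this list after its values had been seen, and its difference from the other chaperones was not tested.

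Ribosomal protein genes were slightly higher as a group in the irradiated library. The median log2 ratio of 113 genes was 0.43, above the medians of all 10000 matched random lists (percentile 100), and that of 1017 transcripts was 0.52, also at percentile 100. Abundant members differed: RPL10A (TBIU054848) had 1491 FPKM in the control and 3405 FPKM in the irradiated library (log2 ratio 1.19), and RPL10 (TBIU010393) had 1218 and 1042 FPKM (log2 ratio -0.22). The 88 genes within 2-fold had a median of 134 FPKM in the control and a median log2 ratio of 0.45. Of the remaining genes, 10 were at least 2-fold higher and 15 at least 2-fold lower, and the 15 lower genes had between 11.8 and 38.7 FPKM in the control, while the higher genes other than RPL10A had between 3.09 and 13.8 FPKM. Genes of ribosomal RNA processing, which the list for organelle and ribosomal RNA matched by their descriptions, were also higher, with a median of 0.56 over 15 genes at percentile 98.7. They included the RNA helicase SPB4 (TBIU011052), with 145 and 303 FPKM (log2 ratio 1.06, and 0.61 for its isoform with the most reads alone). The counting interval of SPB4 was 0.66 to 0.82, which lies under 2-fold. RRP7A (TBIU000131) had a log2 ratio of 1.08. With the overall shift removed, 0 of the 15 genes were at least 2-fold higher and the list median was 0.46. Over 104 transcripts that list had a median of 0.40, at percentile 86.8.

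Pigment enzymes had few measured genes. Of 9 genes, 2 laccase-2 genes were at least 2-fold higher in the irradiated library, the 1 named above and another (lcc2, TBIU017636) with 38.4 and 90.5 FPKM. A laccase-1 gene (yA, TBIU006176) had 15.4 and 4.85 FPKM (log2 ratio -1.49). Of the tyrosinase genes, whose enzyme family makes melanin precursors, the most abundant (tyr1, TBIU016709) had 161 and 141 FPKM (log2 ratio -0.19). The others were less abundant tyr1 genes (TBIU058852, log2 ratio -0.63, and TBIU057804, -0.41) and melC2 (TBIU018172, 0.23). The list median was -0.19 at percentile 16.5 over the genes, and 0.25 at percentile 65.6 over 32 transcripts, so its sign differed between the levels. Of 37 genes on the list for breakdown of plant cell walls, 5 were at least 2-fold higher and 3 at least 2-fold lower, with a median of 0.18 at percentile 71.6, and over 132 transcripts the median was also 0.18, at percentile 59.3. Its text pattern also matched 11 glucan glucosidases and alpha/beta-glucosidases, which can act on fungal wall or storage glucans, and without them 2 of 26 genes were at least 2-fold higher and 2 lower, with a median of 0.21. Among those 26, endoglucanase C (celC, TBIU012976), which cuts cellulose, had 11.9 and 29.4 FPKM (log2 ratio 1.24). The 2 lower genes were xynC (TBIU022988), described as a xylanase, at 17.7 and 8.06 FPKM (log2 ratio -1.05), and the beta-glucosidase bglX (TBIU023650, -1.03). Both were within 2-fold for the isoform with the most reads alone, at -0.42 and -0.11, and other isoforms of xynC are described as a cellobiohydrolase and a kinase. Among the 11, XOG1 (TBIU014111) had a log2 ratio of 1.97 and exgD (TBIU013369) of -1.53.

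Cell cycle and DNA replication genes also went both ways, with 9 of 73 genes at least 2-fold higher and 8 at least 2-fold lower. The cyclin CCN1 (TBIU009042), which acts before DNA synthesis, had 55.7 FPKM in the control and 199 FPKM in the irradiated library (log2 ratio 1.81), and the replication genes PSF2 (TBIU007775), mcm2 (TBIU010882) and mcm3 (TBIU019713) had log2 ratios of 1.36, 1.21 and 1.07. SLD5 (TBIU006772), a partner of PSF2 in the GINS replication complex, went the other way, with 37.1 and 13.4 FPKM over its 2 isoforms (log2 ratio -1.40) and a log2 ratio of -2.65 for the isoform with the most reads alone. Histone H2A (H2A_AGABI, TBIU004504) had 1864 FPKM in the control and 692 FPKM in the irradiated library (log2 ratio -1.43). The list median was 0.15 at percentile 68.6 over the genes and 0.35 at percentile 98.5 over 295 transcripts. The list's text pattern also matched 6 genes with "recycling" or "tetracycline" in their descriptions, and without them 8 of 67 genes were at least 2-fold higher and 7 lower, with a median of 0.22. With the overall shift removed, 7 of the 73 genes were higher and 8 lower.

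Proteases, transporters and cytochrome P450 genes went both ways. Of 114 protease genes, 18 were at least 2-fold higher and 10 at least 2-fold lower (median 0.15, percentile 72.6), and with the overall shift removed 13 were higher and 10 lower. Of 83 transporter genes, 15 were at least 2-fold higher and 6 at least 2-fold lower (median 0.12, percentile 52.3). Among the higher was an amino acid permease gene, DIP5 (TBIU009961), with 44.0 FPKM in the control and 198 FPKM in the irradiated library. A more abundant DIP5 gene (TBIU011595) had 906 and 641 FPKM (log2 ratio -0.50). With the overall shift removed, 11 transporter genes were higher and 8 lower, and 1 of the 6 lower genes, LAC12 (TBIU021384, log2 ratio -1.92), had a counting interval of -0.99 to 0.13. Cytochrome P450 genes, which oxidise many small molecules, numbered 33, of which 4 were higher and 5 lower by 2-fold (median 0.33, percentile 93.8), among them 1 CYP67 gene (TBIU022186) with 36.9 and 171 FPKM and CYP72A15 (TBIU008968) with 330.4 and 84.3 FPKM. Of 49 genes on the respiratory chain list, 5 were higher and 2 lower (median 0.25, percentile 89.5). The higher genes included CCP1, which is also on the antioxidant list, and a cytochrome c-type heme lyase (cchl, TBIU058955, log2 ratio 1.17), matched by the words of their descriptions. The lower genes included alternative oxidase (AOX1, TBIU013210), with 234 and 90.1 FPKM. The genes of transposable elements had a median of -0.22 at percentile 2.68, and 3 of 23 were at least 2-fold lower and none higher. Of these 23, 5 matched as a tetracycline resistance protein, and without them 2 of 18 were at least 2-fold lower, with a median of -0.21.

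The other lists also lay inside the central 95% of their random lists. Glycolysis and citrate cycle genes had a median of 0.12 (39 genes, percentile 55.9), meiosis and spore genes 0.12 (22 genes, percentile 53.0) and housekeeping genes 0.21 (27 genes, percentile 81.5). The glycolysis pattern also matched other aldolases by name, such as an L-threonine aldolase (GLY1, TBIU014514, log2 ratio 1.21). In the housekeeping list an actin gene (ACT_PHARH, TBIU009032) had 132 FPKM in the control and 42.8 FPKM in the irradiated library. Secondary metabolism genes, mostly methyltransferases of several kinds, had a median of -0.28 (14 genes, percentile 4.63). Cell wall genes (75, median 0.07, percentile 37.0), mating and fruiting regulators (15, median 0.07, percentile 43.1), proteasome and ubiquitin genes (105, median 0.06, percentile 30.0) and protein kinases (120, median 0.05, percentile 24.8) had medians above 0 that lay below 0 once the overall shift was removed. Cryptochrome DASH (cry-dash, TBIU017151), a flavoprotein related to the light-driven photolyases, was the only regulator at least 2-fold apart, with 5.14 FPKM in the control and 18.3 FPKM in the irradiated library. No description contained the word hydrophobin, but the regulator list held the fruiting body protein SC3 (TBIU005515), itself a hydrophobin, with 39.7 FPKM in the control and 32.7 FPKM in the irradiated library. Of 21 lists measured, 4 lay outside the central 95% of random lists at the level of transcripts and 3 at the level of genes.

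**Figure D3:**
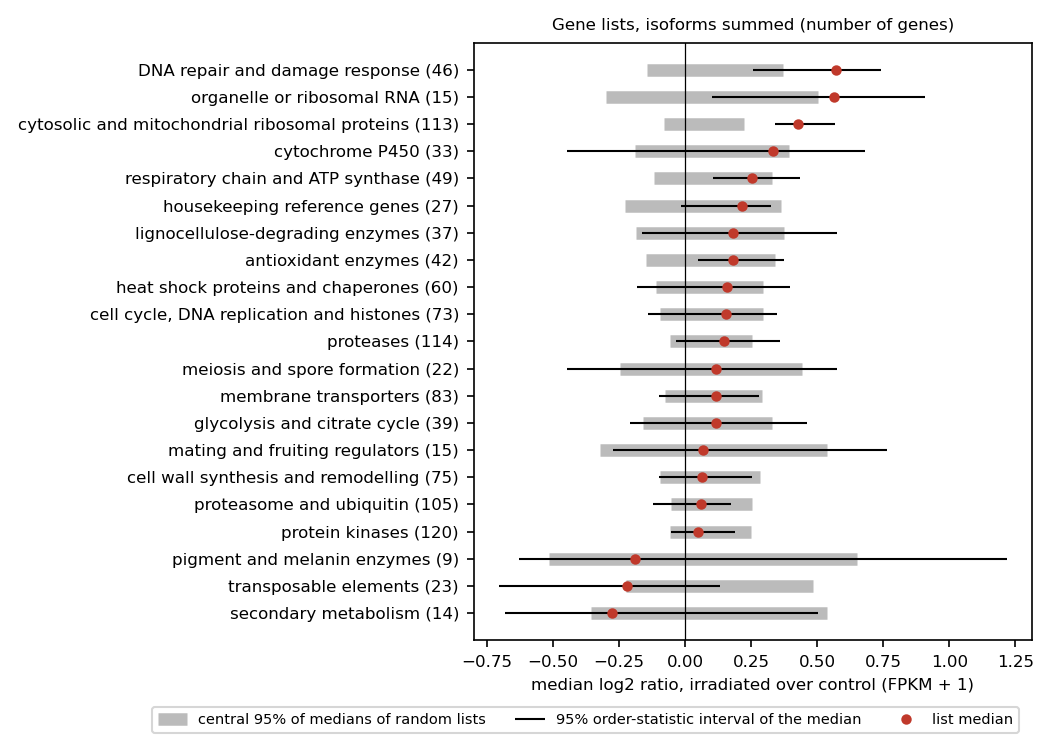
Median log2 ratio of irradiated over control (FPKM + 1) of each gene list (red points, number of genes in parentheses), with isoforms summed and 100 or more scaled reads; black lines are 95% order-statistic intervals of the median and grey bars the central 95% of medians of matched random lists. The medians of DNA repair (0.57), ribosomal RNA processing (0.56, under organelle or ribosomal RNA) and ribosomal protein genes (0.43) lie above their grey bars.

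The authors' deposited table also gave a p-value and a q-value per transcript from a test that it does not name. In the authors' deposited table, a total of 1342 transcripts had a p of 0.05 or less, 653 with a log2 fold change above 0 and 689 below 0, and the q-value was 1 for every transcript. Of these 1342 transcripts, 1231 had a scaled value of 0 on 1 side. The smallest p in the authors' deposited table, 0.000468, belonged to an isoform of the bilirubin oxidase gene (TBIU011885) that was listed at 0 in the control library and at 62.2 FPKM in the irradiated library. With 1 library per group these p-values rest on no measured spread between fruit bodies.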

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

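The alternatives with isoforms summed, with a minimum of scaled reads, with the length trend removed and with the isoform of most reads alone were added after the data had been seen, and the others were planned. The counts of transcripts at least 2-fold higher and lower, 14893 and 12289, stayed within 1.5 times with median-centred ratios, with no filter, with a pseudocount of 0.1, with the authors' scaled values and with isoforms summed. They were 1300 and 1321 at a mean of 10 FPKM or more, 7615 and 5597 with a pseudocount of 5, 3010 and 3025 at 20 or more scaled reads, and 1350 and 1286 at 100 or more scaled reads. With isoforms summed and 100 or more scaled reads they were 769 and 716, with median centring as well 598 and 853, and with the length trend removed instead 786 and 698. Each of these but the pseudocount tests fewer transcripts or genes. The counts alone do not say which genes were shared.

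Of the list medians under the alternatives, 238 stayed inside the 95% interval of the value reported and 14 moved outside it, none of them a list apart from its random lists that turned its sign. The antioxidant median of 0.42 was 0.0785 with isoforms summed, 100 or more scaled reads and median centring. Under the same alternative the ribosomal protein median of 0.52 was 0.32 and the cell cycle median of 0.35 was 0.0499. The ribosomal protein median was 0.30 at a mean of 10 FPKM or more and 0.34 with a pseudocount of 5, and the cell cycle median was 0.0603 at 100 or more scaled reads. Beyond the shift that centring removes, the cause was not tested.

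For named assembled genes, 1009 values stayed inside their counting interval, 226 moved and 1 reversed, PRXQ, at 0.42 for its isoform with the most reads alone. Of the 1009, 206 were ratios of the authors' scaled values. The interval is made from those values, so these 206 could hardly leave it and say nothing about stability. For transcripts named by the planned rule, 141 stayed, 82 moved and 4 reversed, all 4 of them values of Ccnb1ip1, from -5.56 to 0.21 with isoforms summed, 0.21 with 100 or more scaled reads as well, 0.11 with median centring and 0.26 with the length trend removed. Summing adds the reads of its other isoforms. Of the 141 transcript values that stayed, 30 were ratios of the authors' scaled values, with the same limit. Scaling by the library total alone, which had been planned for read counts, was not run since the deposited values hold none.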

Other observations

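All genes and groups in this part were chosen after their values had been seen, and so were all tests except the chance splits of reads and the comparison of genes with 1 isoform and with several.

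The core histone genes and the replication licensing genes lay on opposite sides of the control. All 8 core histone genes had lower values in the irradiated library, 5 of them at least 2-fold, with a median log2 ratio of -1.36. Histone H4 (H4.1, TBIU011518) had 255 FPKM in the control and 67.9 FPKM in the irradiated library, and 1 histone H3 gene (HHT2, TBIU051595) had 401 and 164 FPKM. The 5 genes of replication licensing factors, the helicase loaded before DNA synthesis, all had higher values, with a median of 0.96 and a range from 0.04 to 1.21. With the overall shift of 0.10 removed, the lowest of these, 0.04, lies below 0.

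Aromatic peroxygenase (APO1, TBIU005931), a secreted heme enzyme that oxidises aromatic compounds with peroxide, had 356 FPKM in the control and 1692 FPKM in the irradiated library (log2 ratio 2.25), next in rank after the genes named above. Hydroxyquinol 1,2-dioxygenase (chqB, TBIU021320), which opens aromatic rings, had 10.1 and 37.2 FPKM. A second coq2 gene (TBIU017135), of the assembly cluster of the first, had 115 and 527 FPKM. Among the next in rank below the control, cytochrome P450 3A9 (Cyp3a9, TBIU052845) had 59.3 and 12.3 FPKM and the oxidoreductase ordA (TBIU025839) had 25.6 and 4.75 FPKM, while another ordA gene (TBIU016180), next in rank above the control, had 6.61 and 25.9 FPKM. The nitrogen assimilation regulator nit-4 (TBIU011779) had 477 and 75.5 FPKM, formate dehydrogenase (aciA, TBIU017691) had 144 and 25.4 FPKM, and thiamine thiazole synthase (CC1G_04976, TBIU012006) had 219.9 and 43.1 FPKM. Metacaspase-1 (MCA1, TBIU015056) had 188 and 45.02 FPKM, and the calcium-binding protein Pdcd6 (TBIU017228) had 3379 and 616 FPKM. Of 6 peptidyl-Lys metalloendopeptidase genes, 4 were at least 2-fold lower, with a median of -2.28 over the 6 and a highest value of 0.49.

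The first pattern weighed was the large number of transcripts at least 2-fold apart. Chance splits of each transcript's scaled reads gave 10004 such transcripts on average, 36.8% of the 27182 observed, so counting error may account for part of them and which part stays open. Among transcripts with 100 or more scaled reads the same splits gave 0.1 against 2636 observed, or 0.0038%, which argues against counting error there. Of the 1891 of these in genes with several isoforms, 54.4% belonged to genes within 2-fold once isoforms were summed, so division of reads between isoforms is a candidate explanation for those. Of summed genes with 100 or more reads, 18.2% of those with 1 isoform and 17.8% of those with several were 2-fold apart, a comparison that decides nothing about such division, since summing removes it, and irradiation and differences between fruit bodies stay open, untested.

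In the second pattern, 16 of 35 weaker ribosomal protein copies had a ratio more than 2-fold from that of the strongest copy of the same description. RNA of another organism in unequal amounts may be a source, but of 23 weaker copies of other conserved proteins 0 (0%) differed so much, with an exact upper bound of 14.8% that still covers the 13.2% found among genes with a description of their own, so it cannot be told apart from other sources. Of those 23 copies 12 were elongation factor 1-alpha, set against 1 strongest copy, so they are not independent and the bound is too narrow. Copies that shift together with their strongest copy are not counted. An example is elongation factor 2 (EFT2, TBIU005349), with a log2 ratio of -1.36 that lay -0.18 from its strongest copy. The use of that bound, and a further look at 20 or more scaled reads, followed on seeing the 0%: there 81 of 201 ribosomal copies and 5 of 51 other copies lay beyond 2-fold by their counting intervals. Alleles used unequally by the nuclei of the fungus were not tested, nor was an effect of irradiation, and fragments of 1 gene, which would share a ratio, had no test apart from the pattern itself.

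The third pattern was the lower genes of the small heat shock set, which includes HSP12 genes. For RNA of another organism, the ribosomal protein genes at least 2-fold lower were looked at. The highest control value among them reached 0.0896 of the median control FPKM of the lower small heat shock genes. This cannot decide the question, since the balance of the 2 kinds of transcript in such a source is not known. In the control library, 88 ribosomal protein genes within 2-fold had a median of 134 FPKM, though RPS25A (TBIU002740) reached 5912 FPKM. The hsp16 genes there had between 553 and 2517 FPKM. Reads shared between similar genes were not tested. A hypothesis is that fruit bodies grown from irradiated mycelium hold less of these RNAs, but a difference between 2 fruit bodies or harvests unrelated to irradiation may give the same values and, with 1 library per group, cannot be told apart from it.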
